A study of Homo sapiens with 2 samples.

How the data were processed

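Polyadenylated RNA of SAS cells, an established human line from a squamous cell carcinoma of the tongue, was sequenced 48 hours after lipid transfection with a negative control siRNA or an siRNA against COL17A1. Per the labels, a stranded kit or an equivalent was used and reads were paired-end. The libraries were grouped by the treatment the labels give, 1 per group. The siRNA sequences are not given in the sources used here.

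The deposited table holds a raw count per gene and library, made by the authors and not normalized. STAR, HISAT2 and edgeR and the builds hg38 and GRCh38 are named per the submitters' processing notes, with no versions and no roles, and the counting tool, its strand setting and the annotation release are not given in the sources used here. Counts of genes that overlap others, on the same strand or, if strand was not used, on the opposite one, depend on those settings. Named genes that overlap other loci on their strand, small RNA genes aside, are given beside their values. FPKM values per the file headers stand beside the counts and equalled the count over the deposited exonic size and column total, within 0.0051, for 100% of genes. Totals were 15980152 counts in the control library and 21601195 in the knockdown library. A count of 0 allows up to 0.188 CPM, counts scaled to the library total, in the former and 0.139 in the latter, taking 3 counts as the limit. Intervals and these limits cover counting error only, since reads without molecular identifiers are not independent molecules.

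Counts were scaled with trimmed mean of M-values (TMM) factors of 0.987 for the control and 1.01 for the knockdown library (edgeR 4.0.16, R 4.3.3). The main measure was the log2 ratio of scaled counts, knockdown over control, after adding 0.5 to each count. Of 61806 genes 24705 had at least 1 count, and the 13375 with a mean of at least 1 CPM were tested. Exact Clopper-Pearson 95% intervals of each ratio were computed from both counts, and no p-value across genes. A gene was called higher or lower at 2-fold or more with an interval that excluded 1, which describes these libraries and not the conditions.

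For 44 gene lists, members at least 1.5-fold higher or lower with an interval excluding 1 were counted. The median of each list with at least 5 measured members was placed among 10000 random lists of the same size, matched on mean expression in 10 classes, whose central 95% is called the random band. Terms that the table assigns to 15 to 300 tested genes were ranked in the same way by their distance from 1000 random lists, and the 5 farthest on each side are given. Process terms of 2223 genes were not used here, so membership is partial. The lists, the rule for named genes and the alternatives were fixed before the data were examined, save those named below as later.

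The named genes are COL17A1, the 12 higher and 12 lower genes with a mean of at least 5 CPM whose interval bound nearest to 1 was farthest from 1, up to 4 members of each list by that criterion or, where fewer qualify, by abundance, all hemidesmosome members, and a fixed set of invasion and hypoxia genes. Pseudogenes and loci without a name were passed over, as was XIST, a choice made after its values were seen, and the next gene was taken. Some named genes are not reported here. Of the rest, each gene at least 1.5-fold apart is printed, and part of the others were left out for length after their values were seen.

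Gene type, transcript GC content (99.1% of tested genes) and the longest 3' UTR of at least 50 bases came from GENCODE release 29 on GRCh38, matched by gene identifier. 3' UTRs were searched for 10070 of 10653 genes with a mean of at least 5 CPM, and 16159 words of 7 bases were scored by the residual of the log2 ratio on length, 3' UTR length, both GC contents and abundance. Genes with a word were compared with their 10 nearest genes on these properties, with 2000 bootstrap draws, also in 100 random splits in which the most extreme word was chosen in 1 of 2 equal parts of the genes and measured in the other. Intervals of correlations come from 500 bootstrap draws over genes. Log2 ratios were capped at 3 in size for these fits and for the adjustment below, and the search of words and the classes of length were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

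Alternatives were DESeq2 1.42.0 size factors, total counts, the deposited FPKM with 0.1 added, an offset of 2, other filters and size rules, an assumed coefficient of variation of 0.2, unmatched random lists and list means. An adjustment for length, GC content and abundance, the removal of genes with either 3' UTR word, and a restriction to protein-coding genes were added after the data were seen. The steps were tested on simulated data for this comparison. Of 100 genes simulated with a 3-fold difference among the tested genes, the rule called 94% with counting error alone, beside 24 of 13169 unchanged genes, and 83% with a coefficient of variation of 0.2, beside 348 of 13173. Of 200 lists of unrelated genes drawn from 13375, 3% fell outside the band. A word planted in 775 of 10070 genes with a log2 shift of -0.3 ranked 1 and was chosen in 20 of 20 splits. Rarer words and smaller shifts were not simulated.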

Results

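The data compare the messenger RNA of SAS cells, a human tongue squamous cell carcinoma line, after transfection with an siRNA against COL17A1 or with a negative control siRNA. COL17A1 encodes collagen XVII, a transmembrane collagen of hemidesmosomes, the junctions that anchor basal epithelial cells to the basement membrane. The series concerns COL17A1 in invasion and hypoxia of head and neck squamous carcinoma, and the comparison asks which transcripts differ when COL17A1 is reduced. The control library held 15980152 counts on 21955 genes and the knockdown library 21601195 counts on 22618 genes. With 1 library per group no difference has a replicate check, and each interval in brackets after the log2 ratio of a gene is an exact 95% interval that covers counting error only.

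COL17A1 (ENSG00000065618, GRCh38 chromosome 10, 104031286 to 104085880, minus strand, a locus that also holds MIR936) was 10.5-fold lower in the knockdown library. It had 3116 counts in the control library and 411 in the knockdown library, or 198 and 18.8 CPM after scaling, a log2 ratio of -3.39 [-3.55 to -3.25]. Of 13375 tested genes, 407 were at least 2-fold higher and 481 at least 2-fold lower in the knockdown library. After an adjustment for exonic length, GC content and abundance these counts were 217 and 434. The balance turned to 377 higher and 329 lower without genes that hold the words GCTAATG or TCGGAGA in the 3' UTR, and to 468 and 432 with scaling by total counts. In simulated data with a coefficient of variation of 0.2 between cultures the rule called 348 of 13173 unchanged genes. Part of the calls may thus be variation between cultures. HSP90B1, an endoplasmic reticulum chaperone, lay below the targeted gene at -3.85 [-3.91 to -3.79], with 25209 and 2431 counts. TPM4, a tropomyosin of the actin cytoskeleton, ranked first among the higher genes by its interval bound, at 1.81 [1.76 to 1.87], with 3148 and 15345 counts.

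**Figure D1:**
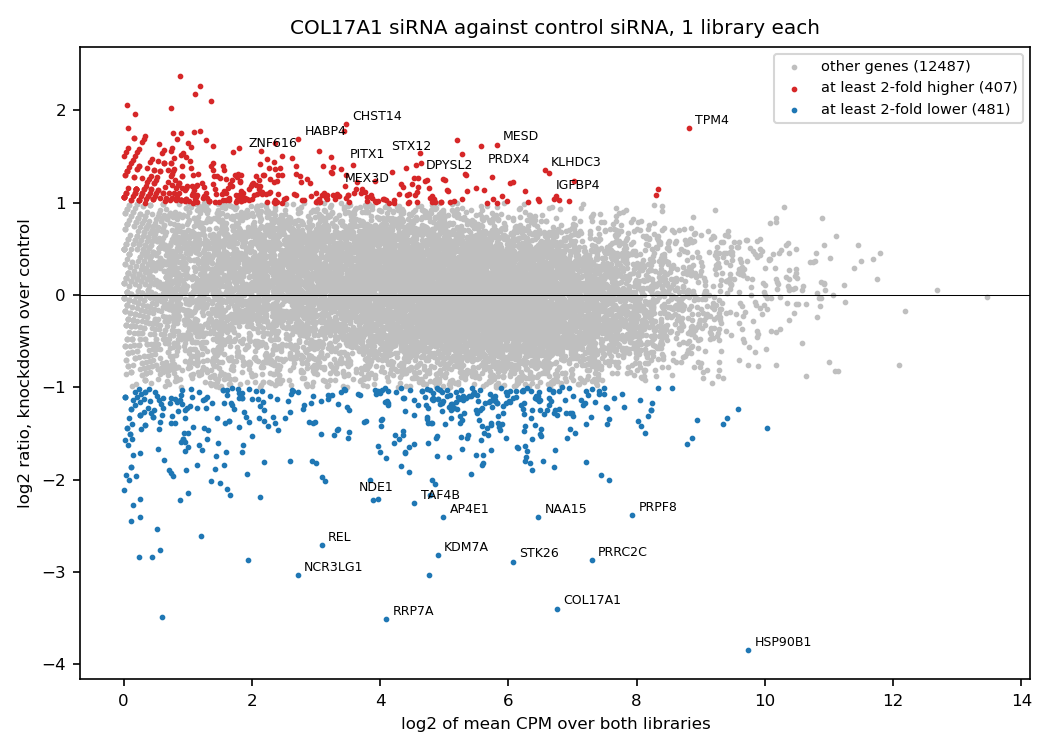
Each point is 1 of the 13375 tested genes, with the log2 of its mean CPM over both libraries on the horizontal axis and its log2 ratio, knockdown over control, on the vertical axis. The 407 higher genes are red and the 481 lower genes blue, and labels mark COL17A1 and the 12 higher and 12 lower genes named by rule, from CHST14 at 1.86 to HSP90B1 at -3.85.

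The 12 lower genes named by rule had log2 ratios from -3.85 to -2.16. RRP7A, a ribosomal RNA processing factor, was at -3.51 [-3.93 to -3.13], and both it and HSP90B1 have pseudogene copies, which leaves their counts uncertain. PRRC2C was at -2.87, the kinase gene STK26 at -2.89, the histone demethylase gene KDM7A at -2.82, and NCR3LG1, a ligand of a natural killer cell receptor, at -3.03. PRPF8, a core spliceosome protein, was at -2.38 with 6471 and 1724 counts. NAA15, a subunit of an N-terminal acetyltransferase, and AP4E1, an adaptor subunit of vesicle transport, were at -2.41 and -2.41. REL, a transcription factor of the NF-kB family, was at -2.71, the TFIID subunit gene TAF4B at -2.25 and NDE1, a regulator of dynein, at -2.16. The 7-base word GCTAATG stood in the annotated 3' UTR of STK26, NCR3LG1, NAA15 and AP4E1, 4 of these 12 genes, and the word TCGGAGA in that of NDE1. AP4E1, REL, TAF4B and NDE1 overlap other annotated loci on their strand.

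The 12 higher genes named by rule had log2 ratios from 1.33 to 1.86. CHST14, a dermatan sulfotransferase, was at 1.86, HABP4, a hyaluronan- and RNA-binding protein, at 1.69 [1.25 to 2.18], and the zinc finger gene ZNF616 at 1.56. MESD and PRDX4, a chaperone and a peroxiredoxin of the endoplasmic reticulum, were at 1.63 and 1.62. The endosomal SNARE gene STX12 was at 1.53 and DPYSL2, a microtubule regulator, at 1.54. KLHDC3, a ubiquitin ligase adaptor, was at 1.35, the homeobox gene PITX1 at 1.44, the RNA-binding protein gene MEX3D at 1.41, and IGFBP4, which binds insulin-like growth factors, at 1.33. After the adjustment PITX1, MEX3D and IGFBP4 were at 0.91, 0.96 and 0.88, under 2-fold. ZNF616, MESD, STX12 and DPYSL2 overlap other annotated loci on their strand. The word TCGGAGA stood in the 3' UTR of TPM4, CHST14, DPYSL2, HABP4, PITX1 and ZNF616, 6 of these 12 genes, and GCTAATG in 0.

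Among genes of hemidesmosomes and basement membrane anchors, DST and COL7A1 were lower beside COL17A1 and KRT5 was higher in the knockdown library. For comparison with counts of list members here and below, 1636 of all 13375 tested genes were at least 1.5-fold higher and 1565 lower. Of 12 measured members 3 were at least 1.5-fold lower, 1 was higher and 8 were neither. Beside COL17A1 these were DST, a linker to the cytoskeleton, at -0.93 [-1.02 to -0.84], COL7A1, the anchoring fibril collagen, at -0.61, and the basal keratin gene KRT5 at 0.60 [0.57 to 0.63]. The laminin genes LAMA3 and LAMB3 were at -0.49 and -0.57, and the integrin genes ITGA6 and ITGB4 at -0.23 and -0.15. PLEC, the plectin linker, was at -0.02, the tetraspanin gene CD151 at 0.52 and KRT14 at 0.34. After the adjustment DST and KRT5 lay under 1.5-fold, at -0.25 and 0.45. KRT14 was then at -0.02, COL7A1 at -0.74 and LAMB3, past 1.5-fold, at -0.78. The list median of -0.36, COL17A1 included, lay at percentile 3.42 of matched random lists, inside their central 95% of -0.38 to 0.24.

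Adhesion and matrix genes at least 1.5-fold apart were mostly lower, while no median of these lists left the random band. The share of lower focal adhesion genes was near that of all tested genes, 1565 of 13375. Of 24 focal adhesion and integrin genes 3 were lower and 0 higher, with the integrin genes ITGA2 and ITGB1 at -0.87 and -0.62 and the kindlin gene FERMT2 at -0.63; the median of -0.26 lay at percentile 3.61. Of 14 collagens other than COL17A1 5 were lower and 0 higher, with COL12A1 at -1.13 and the basement membrane collagens COL4A1 and COL4A2 at -0.97 and -0.61, COL4A1 holding GCTAATG in its 3' UTR. Their median of -0.25 lay at percentile 5.9, and after the adjustment, at -0.31, at percentile 0.52, below the band. Of 18 matrix glycoprotein and crosslinker genes 4 were lower and 0 higher, with FN1, fibronectin, at -0.75 and 86808 and 71458 counts and HSPG2, perlecan, at -0.94 and the laminin genes LAMC1 and LAMB1 at -0.70 and -0.67; the median was -0.15. Of 19 matrix proteases and inhibitors 7 were lower and 1 higher, around a median of -0.03. MMP3, stromelysin, was at -2.22 [-2.54 to -1.92], and the sheddase genes ADAM17 and ADAM10 at -1.25 and -0.91. ADAMTS1, a secreted protease, was at -1.04. MMP14, a membrane-bound protease whose 3' UTR holds TCGGAGA, was at -0.27 and MMP2 at 0.36, and for MMP9, with 6 and 9 counts, no difference was detectable at this depth. After the adjustment ITGB1, FERMT2, COL4A2, FN1, LAMC1, LAMB1 and ADAM10 lay under 1.5-fold, at -0.23, -0.34, -0.42, -0.44, -0.54, -0.38 and -0.52. COL4A1, ADAM10 and MMP2 overlap other annotated loci on their strand.

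Epithelial and mesenchymal genes went both ways. CDH1, E-cadherin, was at 0.03 [-0.03 to 0.09], CDH2, N-cadherin, at -0.85 [-1.11 to -0.59] and VIM, vimentin, at 0.67 [0.40 to 0.95]. Of 16 measured mesenchymal genes 4 were higher and 4 lower, with the cadherin gene CDH11 at -1.44, and the median was 0.20. Of 21 epithelial junction genes 3 were higher and 4 lower, with the claudin gene CLDN4 at 1.00, the GTPase gene RAB25 at 0.72 and the tight junction scaffold gene TJP1 at -0.72, and the median was 0.03. Of 12 desmosome genes 2 were lower and 0 higher, with the cadherin genes DSG2 and DSG3 at -0.69 and -0.60 and DSP, desmoplakin, at -0.57, and the median was -0.08. Of 18 basal keratinocyte genes 4 were higher and 0 lower, with a median of 0.22; TP63, the basal epithelial transcription factor, was at -0.47 and EGFR at -0.42. Of 14 keratinocyte differentiation genes 5 were higher, 0 lower and 9 neither, the higher ones including CSTA, a protease inhibitor of the cornified envelope, at 0.71, S100A9 at 0.69 and KRT10 at 0.79. Their median of 0.52 lay at percentile 99.83, and at 0.20, inside the band, after the adjustment. After the adjustment RAB25, TJP1, DSG2, DSG3 and S100A9 lay under 1.5-fold, at 0.36, -0.39, -0.38, -0.43 and 0.16. CDH1, CDH2, CDH11 and TJP1 overlap other annotated loci on their strand.

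**Figure D2:**
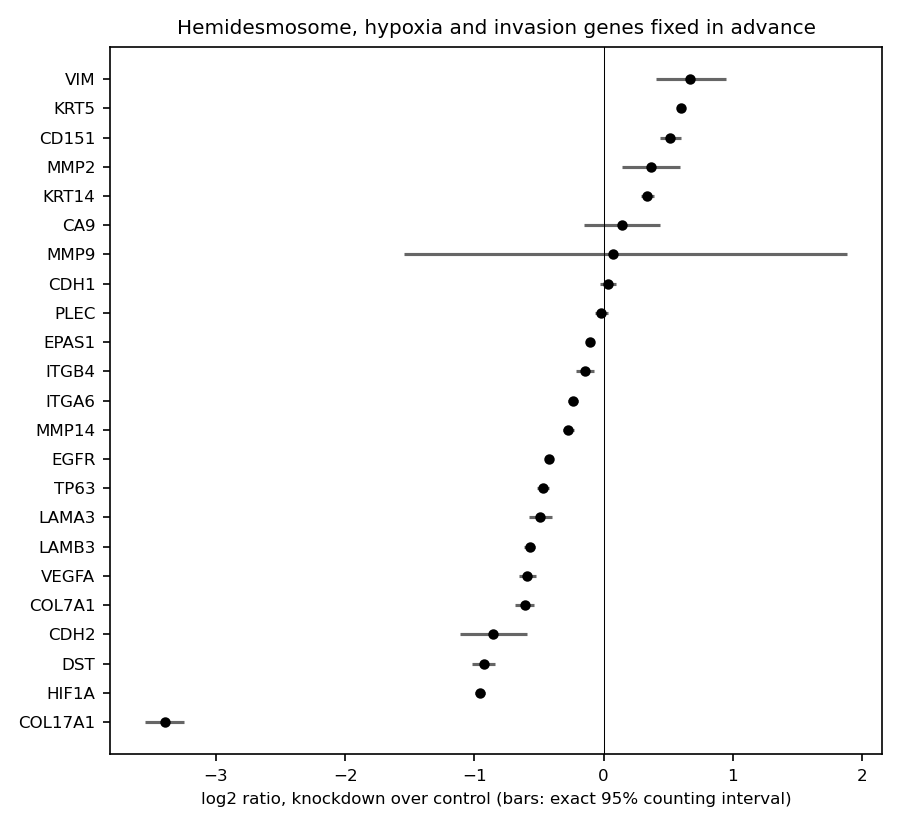
Points are log2 ratios, knockdown over control, of hemidesmosome genes and of invasion and hypoxia genes fixed in advance, and bars are exact 95% counting intervals. COL17A1 lies at -3.39, HIF1A at -0.96, CDH1 at 0.03 and VIM at 0.67, and the bar of MMP9 is wide because it rests on 6 and 9 counts.

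The hypoxia response list was centred near 0, while the transcript of HIF1A was lower in the knockdown library. HIF1A, the oxygen-regulated subunit of hypoxia-inducible factor, was 1.94-fold lower with 11990 and 8588 counts, a log2 ratio of -0.96, and -0.76 after the adjustment. EPAS1, its paralog, was at -0.10. Of 32 measured hypoxia response genes 4 were higher and 4 lower, with a median of -0.02 at percentile 44.6. CA9, carbonic anhydrase IX, was at 0.14 [-0.15 to 0.43] and VEGFA, the angiogenic factor, at -0.59 [-0.66 to -0.53]. KDM3A, a histone demethylase, was at -1.39, the nuclear receptor gene RORA at -1.33, NDRG1 at -0.65 and the lipoprotein receptor gene VLDLR at 1.21. Of 11 genes of the HIF pathway itself 3 were lower and 0 higher, with the coactivator genes CREBBP and EP300 at -1.12 and -0.78 and a median of -0.17 at percentile 16.1. GCTAATG stood in the 3' UTR of VEGFA, KDM3A, RORA, VLDLR and CREBBP. After the adjustment VEGFA and EP300 lay under 1.5-fold, at -0.52 and -0.51. HIF1A, RORA and NDRG1 overlap other annotated loci on their strand.

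The lists of oxidative phosphorylation, ribosomal, mitochondrially encoded and glycolysis genes had medians above those of matched random lists. Of 28 nuclear oxidative phosphorylation genes 8 were higher and 1 lower, with the complex I genes NDUFB8 and NDUFA4 at 0.88 and 0.75, COX5B of complex IV at 0.85, and NDUFS1, whose 3' UTR holds GCTAATG, at -0.75. Their median was 0.43, at percentile 100. Of 33 ribosomal protein genes, uncertain because of their many processed pseudogenes, 11 were higher and 0 lower, with RPL13 at 0.76, RPS27 at 0.70 and RPS19 at 0.68 and a median of 0.47 at percentile 100. Mitochondrially encoded genes had a median of 0.41 at percentile 99.84, with MT-ND6 at 0.74 the single member at least 1.5-fold higher, and mitochondrial genes took 0.777% of counts in the control library and 0.988% in the knockdown library. Of 18 glycolysis genes 2 were higher and 0 lower, with PGAM1 at 0.66, PFKL at 0.70 and HK2 at -0.54, and a median of 0.22 at percentile 98.4. After the adjustment the medians were 0.39 and 0.38, above the band, for oxidative phosphorylation and ribosomal genes. They were 0.16 and 0.12, inside it, for mitochondrially encoded and glycolysis genes. The adjustment took the deposited exonic size as length, with medians of 3154, 3687 and 784 bases for oxidative phosphorylation, ribosomal and mitochondrially encoded genes. That size can exceed the length of the transcripts present, so part of a length trend may remain in these medians. After the adjustment COX5B, NDUFS1, RPL13, RPS27, RPS19, MT-ND6, PGAM1 and PFKL lay under 1.5-fold, at 0.52, -0.43, 0.49, 0.39, 0.46, 0.47, 0.44 and 0.49. NDUFB8 and NDUFS1 overlap other annotated loci on their strand.

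The lists of interferon-stimulated and antigen presentation genes had medians above those of matched random lists. Of 26 measured interferon-stimulated genes 9 were higher and 1 lower, with the ubiquitin-like modifier gene ISG15 at 1.23 [0.96 to 1.52] and the antiviral genes IFIT1 and OASL at 1.09 and 1.01. The lower member, the RNA sensor gene DDX58, was at -2.01 [-3.33 to -0.93] on 27 and 9 counts and overlaps another locus on its strand, so its value is uncertain. The list median was 0.52 at percentile 99.99, and 0.51 after the adjustment. Of 14 antigen presentation genes 7 were higher and 0 lower, with the immunoproteasome genes PSMB9 and PSMB8 at 1.13 and 0.86, and the class I genes HLA-B and HLA-C, uncertain as close paralogs, at 0.94 and 0.82. Their median was 0.61 at percentile 100, and 0.44 after the adjustment. After the adjustment ISG15 and HLA-C lay under 1.5-fold, at 0.56 and 0.42. DDX58, PSMB9 and HLA-B overlap other annotated loci on their strand.

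The lists of cytokine genes, of feedback genes of growth factor signalling and of RNA interference genes had medians below those of matched random lists. Of 23 NF-kB targets and inflammatory cytokines 5 were lower and 1 higher, with a median of -0.36 at percentile 0.28. IL1A, interleukin 1 alpha, was at -1.44 [-1.47 to -1.41] with 24227 and 12430 counts, the cytokine genes LIF and CSF2 at -1.05 and -0.79, and PTGS2, a cyclooxygenase, at -0.84. Of 23 EGFR, RAS and MAPK feedback genes 4 were lower and 0 higher, with the EGFR ligand gene EREG at -1.19, the inhibitor genes SPRY4 and SPRY2 at -1.07 and -0.70 and the phosphatase gene DUSP4 at -0.70. The median was -0.33 at percentile 0.705. Of RNA interference genes 4 of 13 were lower and 0 higher, with TNRC6A at -1.28, TNRC6C at -1.16, the microprocessor gene DGCR8 at -1.19 and DICER1 at -0.85, and a median of -0.46 at percentile 0.28. GCTAATG stood in the 3' UTR of EREG, SPRY2, TNRC6A and TNRC6C, and the medians of the feedback and RNA interference lists lay inside the band once genes with either word were left out. After the adjustment DICER1 lay under 1.5-fold, at -0.35. TNRC6C overlaps another annotated locus on its strand.

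The lists of heat shock, NRF2 target and cholesterol synthesis genes had medians above those of matched random lists, with exceptions among their members. Of 14 heat shock genes 4 were higher and 0 lower, with the small heat shock genes HSPB8 and HSPB1 at 1.77 and 0.73 and HSPA1A and HSPA1B, uncertain as near-identical copies, at 1.25 and 0.99, and a median of 0.33 at percentile 99.4. Of 19 NRF2 targets 4 were higher and 2 lower, with AKR1C3 at 1.49, the ferritin gene FTL at 0.79 and the thioredoxin reductase gene TXNRD1 at -0.76 and the cystine transporter gene SLC7A11, which holds GCTAATG, at -0.64, and a median of 0.30 at percentile 98.7. Of 22 cholesterol synthesis genes 3 were higher and 2 lower, with INSIG1 at 1.02, MVK, mevalonate kinase, at 0.71, STARD4 at -0.85 and CYP51A1, lanosterol demethylase, at -1.37, and a median of 0.24 at percentile 98.2. After the adjustment the NRF2 and cholesterol medians were 0.12 and 0.17, inside the band. After the adjustment HSPB1, FTL and SLC7A11 lay under 1.5-fold, at 0.21, 0.33 and -0.28. HSPB8, HSPA1B, TXNRD1 and CYP51A1 overlap other annotated loci on their strand. With random lists not matched on expression the heat shock, NRF2, cholesterol and glycolysis medians lay inside the band, as did the NRF2 and cholesterol lists by their means. In all, 13 of 40 lists with at least 5 measured members lay outside the band, 10 above and 3 below, where 2 are expected of unrelated genes. After the adjustment 11 lay outside, 5 above and 6 below, of which 8 were outside in both.

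**Figure D3:**
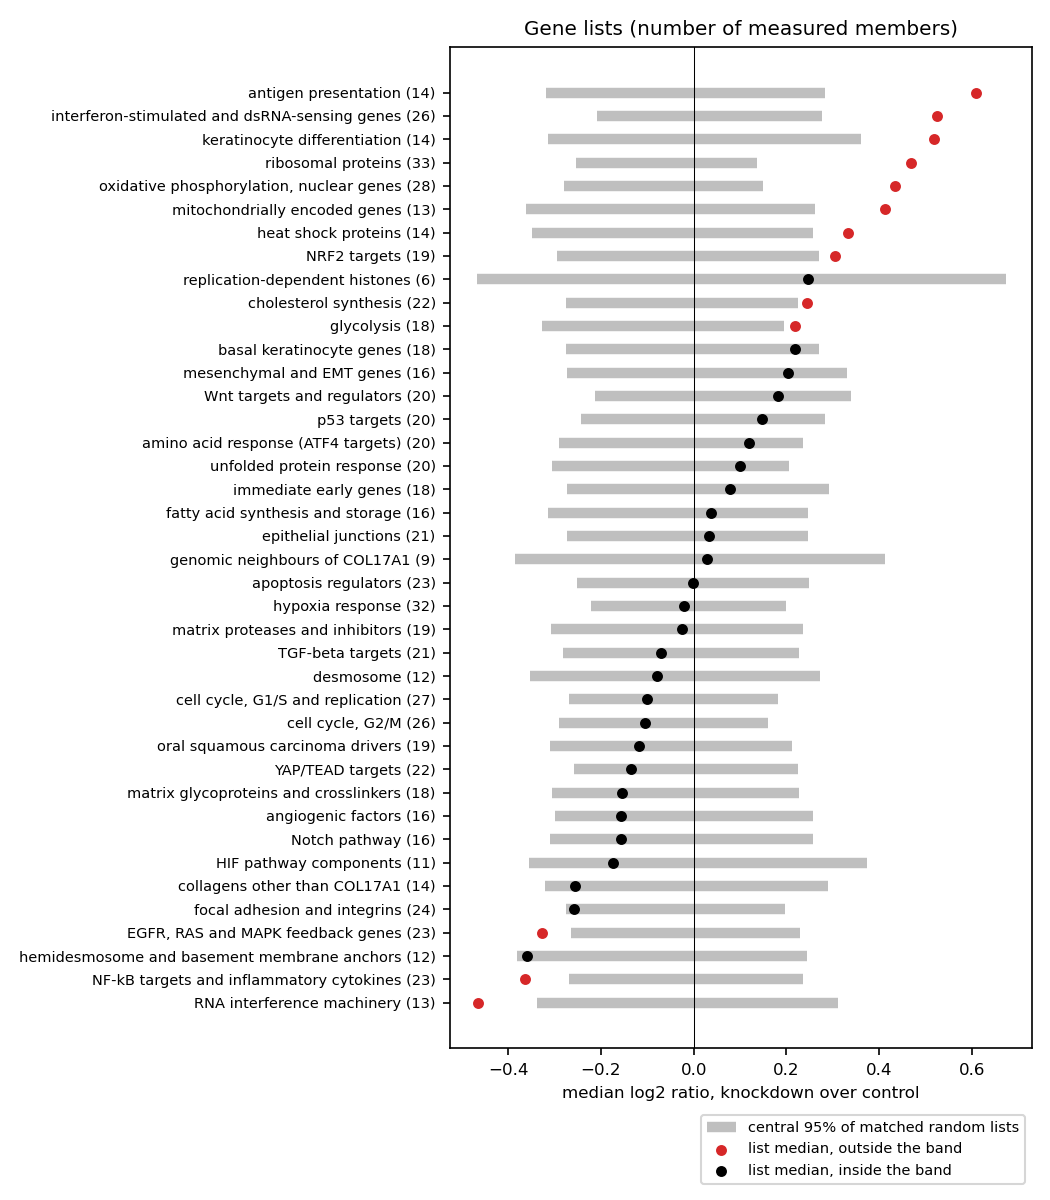
Points are median log2 ratios, knockdown over control, of the 40 gene lists with at least 5 measured members, and grey bars span the central 95% of 10000 random lists matched on mean expression. The 13 lists outside their bars are red, from antigen presentation at 0.61 to RNA interference machinery at -0.46.

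Among 1693 annotation terms, structural constituents of the ribosome stood farthest above matched lists, 257 genes with a median of 0.42, followed by translation at 0.39, the pathway of chemical carcinogenesis by reactive oxygen species at 0.35, cytoplasmic translation at 0.45 and oxidative phosphorylation at 0.42. A gene can belong to several terms and shared genes were not removed, so the terms named here are not independent of each other. ATP hydrolysis activity, a term listed as obsolete, stood farthest below, 155 genes with a median of -0.38. Guanyl-nucleotide exchange factors at -0.21, DNA helicases at -0.44, the chromosome at -0.22 and regulation of small GTPase signalling at -0.29 came next. After the adjustment oxidative phosphorylation stood farthest above, at 0.30, and structural constituents of the ribosome were at 0.23. Translation, at 0.21, and cytoplasmic translation, at 0.30, were then no longer among the 5 farthest above, where complex I assembly, at 0.42, and diabetic cardiomyopathy, at 0.24, took their place. ATP hydrolysis activity, at -0.25, and the chromosome, at -0.19, were still among the 5 farthest below. Exchange factors, helicases and small GTPase regulation, at -0.11, -0.25 and -0.18, gave way to peptidyl-lysine trimethylation at -0.67, translation factors at -0.47 and the histone methyltransferase complex at -0.35.

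Markers of other cell types were rarely measured, with 4 of 16 fibroblast, 1 of 12 endothelial, 4 of 16 leukocyte and 2 of 12 muscle genes above the filter. The fibroblast gene FAP was at -0.72 and COL1A1, on 15 and 32 counts, at 0.59 [-0.31 to 1.61], an interval that includes 0. The endothelial gene EGFL7 was at 0.62, the monocyte genes CD14 and CSF1R at 0.80 and -0.62 and the troponin gene TNNT1 at 0.54. After the adjustment FAP, EGFL7 and CD14 lay under 1.5-fold, at -0.44, 0.04 and 0.43.

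Log2 ratios followed exonic length, GC content and 3' UTR words across genes, which are not independent replicates. Over 5 classes of exonic length the median log2 ratio was 0.37 in the shortest genes and -0.25 in the longest. The partial rank correlation with length given GC content was -0.392, and with GC content given length 0.375. The median exonic length was 6645 bases for the lower genes and 2631 for the higher genes, against 5182 for all tested genes. GCTAATG stood in the 3' UTR of 39.8% of the 374 searched lower genes, 4.32% of the 278 higher genes and 8.40% of all 11671 searched genes. In COL17A1 mRNA it stands in the coding sequence of exon 15 of 56 (chromosome 10, 104059638 to 104059644) and of exon 18 (104055798 to 104055804), there as GCTAATGA. TCGGAGA stood in 6.47% of the higher genes, 1.60% of the lower genes and 2.18% of all. Both words were picked as the most extreme on their side in a search of these same log2 ratios. Their shares among the higher and lower genes thus follow in part from that choice.

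**Figure D4:**
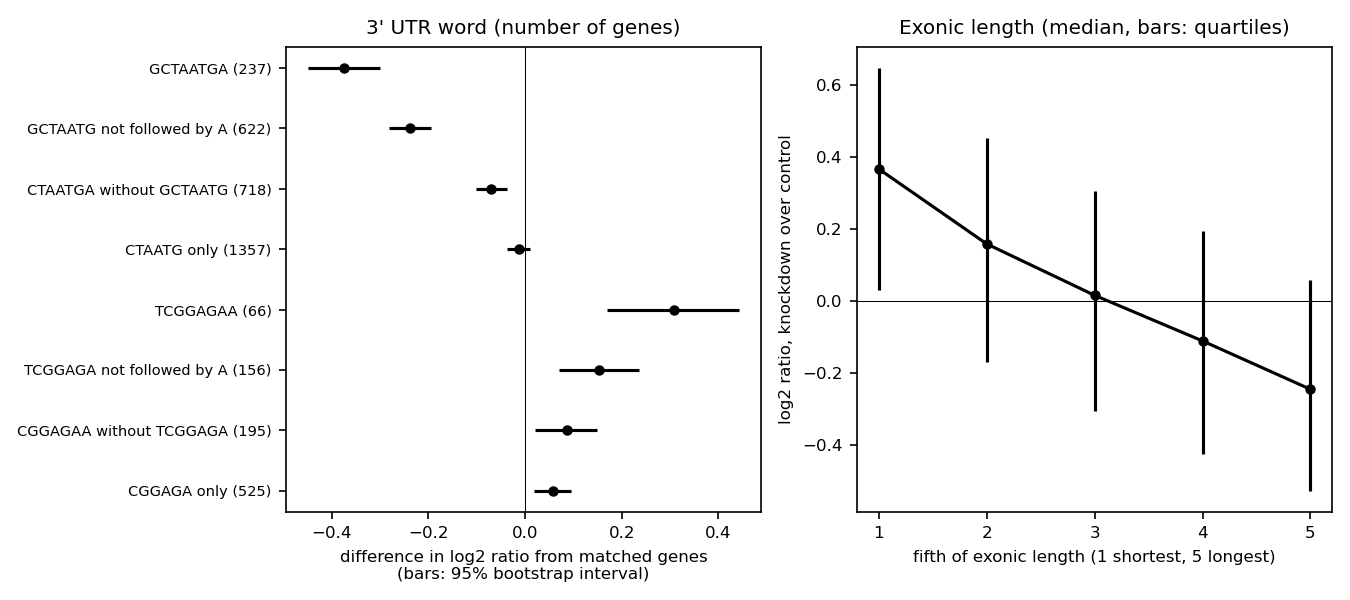
The left panel plots, for genes grouped by 3' UTR word, the difference in log2 ratio from matched genes with 95% bootstrap intervals, from -0.37 for GCTAATGA to 0.31 for TCGGAGAA. The right panel plots the median log2 ratio, with quartiles as bars, in 5 classes of exonic length, from 0.37 in the shortest to -0.25 in the longest genes.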

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

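The log2 ratio of COL17A1 lay between -3.41 with DESeq2 size factors and -3.31 with the deposited FPKM, within its counting interval. The counts of genes followed the filter and the size rule by construction. Without a filter 728 genes were higher and 817 lower, and at a mean of at least 5 CPM 149 and 317. At 1.5-fold 1636 were higher and 1565 lower, and with the interval bound beyond 2-fold 48 and 234. With an assumed coefficient of variation of 0.2 there were 331 higher and 456 lower. That setting widened the intervals and left the ratios as they were. A call already needed 2-fold, so mainly genes with wide counting intervals could drop out. These counts therefore cannot decide how many calls are variation between cultures. The adjustment for length, GC content and abundance, chosen after the data were seen, left 217 higher and 434 lower, with 162 and 335 shared with the unadjusted calls, and moved 131 of 197 named genes beyond their counting intervals. The cause was not tested. With the deposited FPKM, 0.1 added, 19 of the 197 named genes moved so, REL among them. Ratios of genes with low FPKM shrank in that setting. CDH11, RORA and VLDLR were among the called genes that then lay under 2-fold, as was CCND1, whose FPKM is not low. Higher calls outnumbered lower ones with total counts, 468 against 432, with the deposited FPKM, 344 against 335, and without genes with either 3' UTR word, 377 against 329, and lower calls outnumbered higher ones with DESeq2 size factors, 506 against 366. Outside the random band lay 13 lists under each scaling, offset and filter, and 11 with unmatched random lists and after the adjustment. Oxidative phosphorylation, ribosomal, interferon-stimulated, antigen presentation and NF-kB lists stayed outside on their side in 10 of 10 settings. No named gene or list that was called turned its direction. A restriction to genes the table marks as protein-coding was not run, since it gives no gene type, and by GENCODE type 288 were higher and 376 lower. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not run for that reason. Depth limits genes of few counts, such as MMP9 with 6 and 9.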

Other observations

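The tests of matched genes in random splits, of chance and of pairing outside the 3' UTR were chosen after the result was seen, and those of 8-base sites after the words had been found but before their values. Intervals in brackets for 3' UTR words and for correlations are 95% bootstrap intervals over genes. Cell cycle genes went both ways. Of 27 G1/S and replication genes 2 were higher and 4 lower, with the licensing factor gene CDT1 at 1.24, cyclins CCND1 and CCNE2 at -1.01 and -0.87 and the checkpoint gene CLSPN at -0.90, and of 26 G2/M genes 3 were higher and 1 lower, with BIRC5, survivin, at 0.66, UBE2C at 0.62, the spindle gene NUSAP1 at 0.90 and the kinesin gene CENPE at -0.95. Of 20 p53 targets 5 were higher and 1 lower, with the apoptosis genes BBC3 at 1.10 and BAX at 0.68, PHLDA3 at 0.81, and AEN, a nuclease gene with GCTAATG in its 3' UTR, at -2.21. Of 23 apoptosis regulators 5 were higher and 3 lower, with APAF1, the apoptosome scaffold, at -1.53, the inhibitor gene XIAP at -0.76 and BAD at 0.77. Of 19 oral carcinoma drivers 2 were higher and 4 lower, with CDKN2A, which encodes p16, at 1.00, PIK3CA at -0.82 and the histone methyltransferase gene NSD1 at -0.94. Of 9 genes near COL17A1 on chromosome 10 2 were lower and 0 higher, with the kinase gene SLK at -1.27 and NEURL1 at -0.69. Of 6 histone genes 1 was higher, H2BC5 at 0.78, and 0 lower. Medians were -0.10, -0.11, 0.15, -0.00, -0.12, 0.03 and 0.25 in that order, all inside the random band. After the adjustment BIRC5, UBE2C, CENPE, BAX, PHLDA3, XIAP, BAD, PIK3CA, NSD1 and H2BC5 lay under 1.5-fold, at 0.57, 0.34, -0.53, 0.31, 0.46, -0.56, 0.20, -0.36, -0.55 and 0.42. NUSAP1, PHLDA3, NSD1, NEURL1 and H2BC5 overlap other annotated loci on their strand.

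Signalling and metabolic lists inside the band were mixed. Of 22 YAP/TEAD targets 4 were lower and 1 higher, with TGFB2 at -1.54 and the phosphatase gene PTPN14, which holds GCTAATG, at -1.36 and F3, tissue factor, at -0.82, and of 21 TGF-beta targets 3 were lower and 2 higher, with ID3 at 0.84. Of 20 Wnt genes 7 were higher and 1 lower, with the ligand genes WNT10A and WNT3A at 1.04 and 1.04 and FZD7 at 0.83, and of 16 Notch genes 3 were higher and 2 lower, with the ligand gene JAG1 at -0.66, DTX3L at -1.07 and RFNG at 0.91. Of 16 angiogenic factors 5 were lower and 1 higher, with FGF2, which holds GCTAATG, at -0.88, NRP2, which holds it too, at -1.07, SEMA3C at -0.64 and VEGFB at 0.70. Of 18 immediate early genes 1 was higher and 1 lower, with JUND at 0.74 and KLF6, which holds GCTAATG, at -0.63. Of 20 unfolded protein response genes 4 were higher and 1 lower, with CALR, calreticulin, at 0.83, MANF at 0.71 and SDF2L1 at 1.04 beside HSP90B1 at -3.85. Of 20 amino acid response genes 4 were higher and 3 lower, with the folate enzyme gene MTHFD2 at -1.33 and PHGDH, of serine synthesis, at 0.71, and of 16 lipid synthesis genes 1 was higher and 0 lower, with DGAT1 at 0.72. Medians were -0.14, -0.07, 0.18, -0.16, -0.16, 0.08, 0.10, 0.12 and 0.04 in that order, and the YAP/TEAD and Notch medians lay below the band after the adjustment, at -0.17 and -0.25. After the adjustment ID3, WNT3A, JAG1, RFNG, SEMA3C, VEGFB, JUND, MANF, SDF2L1 and DGAT1 lay under 1.5-fold, at 0.47, 0.51, -0.51, 0.52, -0.51, 0.25, 0.05, 0.54, 0.33 and 0.38. TGFB2, PTPN14, FGF2, MTHFD2 and DGAT1 overlap other annotated loci on their strand.

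Genes with GCTAATG in the 3' UTR were lower in the knockdown library, the lowest score of 16159 words. Against length, composition or abundance as the source, GCTAATG was the lowest word in 1 part of the genes in 100 of 100 random splits, and genes with it in the other part lay -0.28 [-0.33 to -0.22] from matched genes (medians over splits), with the interval below -0.1 in 100 splits. Against chance, 0 of 200 random reassignments gave a score as low as its -16.7, the lowest being -5.31. Genes with GCTAATGA lay a further -0.14 [-0.22 to -0.05] from those with GCTAATG not followed by A, and COL17A1 mRNA holds GCTAATGA, which is consistent with seed-directed silencing by the COL17A1 siRNA, as a hypothesis. For the 12 lower genes named by rule, pairing elsewhere cannot be told apart from other sources, since the median stretch shared with COL17A1 around the word was 0 bases in them and in random genes of like length, and an effect of COL17A1 loss itself stays open, untested with 1 siRNA against it.

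Genes with TCGGAGA in the 3' UTR were higher in the knockdown library, the highest score of 16159 words. Against chance, 0 of 200 random reassignments of the values left after a fit of length, composition and abundance reached its score of 6.32, the highest being 4.78. The reassignments test chance only. That the score was taken after the fit argues against these properties as the whole source only as far as the fit captures them. Whether these properties leave a difference under 0.1 or a larger one cannot be told apart. The word was the highest in 1 part of the genes in 64 of 100 random splits. In the other part genes with it lay 0.19 [0.08 to 0.29] from matched genes (medians over these splits), with the interval above 0.1 in 18 and below it in 0. A candidate explanation is seed-directed silencing by the control siRNA in the control library. Genes with TCGGAGAA lay a further 0.16 [-0.01 to 0.31] from those with TCGGAGA not followed by A, with 66 genes in the smaller class. That interval includes 0, so a further step with the added A cannot be told apart from none. Against matched genes these classes lay at 0.31 [0.17 to 0.44] and 0.15 [0.07 to 0.24], in intervals that ignore the choice of the word. Silencing by the control siRNA is not settled by this, and an effect of COL17A1 loss was not tested.

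Long genes were lower and short genes higher, with a Spearman's rho of -0.432 across 10653 genes, which are not independent replicates. Without CTAATG and CGGAGA in the 3' UTR rho was -0.462 [-0.481 to -0.441]. This argues against 3' UTR sites of these words as the source. Genes with other words, or with sites in other transcript regions, were not left out. After thinning of the knockdown library to the control total rho was -0.432 [-0.449 to -0.417]. Random thinning keeps the expected ratios of genes up to a common factor, so this value cannot decide on depth. The partial correlation given GC content was -0.392 [-0.408 to -0.375], which argues against GC content alone. That with GC content given length was 0.375 [0.358 to 0.392], of like size. RNA integrity or fragment size was not tested, since coverage along transcripts was not used here, and with 1 library per group it may differ with the siRNA. An effect of COL17A1 loss on long genes stays open as well, untested.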
